A study of Rattus norvegicus with 48 samples.

How the data were processed

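Total RNA of Fao cells was measured on 48 Agilent rat arrays, 1 array per sample, 8 of vehicle, 20 of palmitate (PA) and 20 of palmitate with metformin and sodium salicylate (PA+Met+NaS). Group and replicate number were taken from the sample labels. Per the labels' protocols, material from 800 ng of RNA was labelled with Cy3 and spike-in RNA was added. The extraction protocol in the labels speaks of adipocytes of another line, whereas each sample's own labels name Fao hepatoma cells, and the sample labels were followed. The labels describe the replicates as independently grown and harvested, but do not tie arrays to days.

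Per the file headers, the authors scanned the arrays in 1 colour and made the intensity values with Agilent Feature Extraction (version 9.5.1 in the submitters' processing notes), which fitted a background surface and removed spatial and multiplicative trends within each array. The deposited processed signal is thus an intensity corrected within the array and not scaled between arrays, and spots at background carry surrogate values, per the file headers. The deposited mean spot signal and local background are uncorrected intensity values. The deposited flags for outlier, saturated and well-above-background spots are 0 or 1. The deposited value table of the series was set against each array's scanner values and equalled the processed signal within 0.5% at up to 45018 features per array, so it is on the linear scale, uncentred, with column medians from 3.48 to 33. Every one of its columns matched a sample.

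Each array held 43379 non-control spots of 41012 probes, and 3 garbled spot lines were skipped. The log2 of the processed signal minus the array's 75th percentile over all non-control spots was the value analysed. Spots with an outlier flag were left out, which removed 0.548% of the values, and saturated spots were kept. Spots of a probe were averaged, and the 23054 probes well above background on at least 8 arrays were kept. The percentile was first taken over spots without an outlier flag. This departed from the fixed design and was corrected to all non-control spots after results had been seen, and the earlier version is kept as an alternative. Probe names were updated through a RefSeq gene table of the GRCr8 assembly, used for names only. Of the probes, 11045 were named through an accession, 5002 by a current symbol, 3339 through a synonym and 463 from the description, 2680 kept the array's own name and 18483 had no gene name. A gene with several probes was represented by the brightest, and 19790 items resulted, 11497 named genes and 8293 unnamed probes. Where a probe was not well above background on every array, the number of arrays is given beside its change. A gene below background on every array of a group has only a lower bound, taken from the mean of the bright group against, on each array of the dim group, the higher of the lowest signal among probes well above background and the probe's own signal. Coordinates are those of the array files (rn4, 1-based).

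All 48 arrays entered 1 limma fit (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all items and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 29 lists. Of 31 lists, 26 of pathways and 5 of markers of other cell types, those of stellate and endothelial cells had 2 and 3 measured members, under the minimum of 5, and were not tested. Missing values were filled with their fitted values for the list tests and for the splits of the arrays, so the counts given with the splits differ slightly from the others. The splits were 100 for each result, the real one included. Slide and scan day, read from the file headers, were fitted as blocks, and values were also taken within each slide or day that held at least 2 arrays of each group.

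Before the data were examined, the groups, the tests, the gene lists, most alternatives and the rule for naming genes were fixed. The rule took the 10 largest rises and 10 largest falls in PA against vehicle and in PA+Met+NaS against PA among genes past the threshold, with a symbol not starting with LOC or RGD and a probe well above background on every array of at least 1 of the groups compared. It took 5 and 5 for PA+Met+NaS against vehicle, 5 and 5 for genes that moved back, up to 4 measured members of each list with the smallest adjusted p, and Pck1, G6pc, Insr, Irs1, Irs2, Cpt1a, Pdk4, Ppargc1a and Scd always. Not every gene it took is reported here. Alternatives covered the scaling, normexp with an offset of 50 followed by quantile normalisation, the filter on dim probes, the rule for probes, array weights, the samples in the fit, the replicate number, slide and scan day as blocks, a 1.5-fold minimum and leaving out each vehicle array. The alternatives with array position, those that pair the slide with another choice, and those without the 3 brightest arrays, without PA replicate 17 or with the percentile over spots without an outlier flag were added after seeing the data.

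The fits were tested on simulated data made from the real spread of 19790 items with 200 changed genes, 100 at each size. A log2 change of 0.5 was recovered for 35%, 62% and 35% of genes in PA against vehicle, PA+Met+NaS against PA and PA+Met+NaS against vehicle, and a change of 1 for 84%, 92% and 83%. With slide as a block these were 71%, 83% and 72%, and 93%, 98% and 92%. False calls numbered 0, 0 and 3 of 19558 unchanged genes without the block and 3, 13 and 8 with it. For genes that moved back, 35% and 83% were recovered without the block and 71% and 93% with it. A list of 32 genes shifted by 0.25 log2 passed camera in each simulation. Of the other lists 0 passed without the block, and 1, 5 and 2 passed with it. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.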

Results

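Fao cells, a well-differentiated line of rat hepatoma cells, were profiled on 48 one-colour Agilent rat arrays, each hybridised with material labelled from 800 ng of total RNA. The 48 arrays fell into 8 vehicle arrays, 20 arrays of cells given palmitate (PA) and 20 of cells given palmitate together with metformin and sodium salicylate (PA+Met+NaS, called the combination here). Palmitate is the commonest saturated fatty acid of plasma and was given at 0.075 mM. Metformin, a glucose-lowering drug, was given at 0.25 mM and salicylate, an anti-inflammatory drug, at 2 mM. Per the labels, treatment lasted 24 h in medium with 10% serum and a further 24 h in glucose-free medium with 0.1% albumin, 2 mM pyruvate and 20 mM lactate, substrates from which liver cells can make glucose. The series asks how palmitate disturbs glucose output by liver cells. The labels describe the replicates as grown and harvested independently over 8 days, with 1 replicate per array and no note of which array came from which day.

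The 75th percentile of processed signal ran from 75.9 to 672 over the 48 arrays, and between 19757 and 26954 of the 43379 non-control spots were well above background. Between 13 and 488 spots per array were saturated. Pairs of vehicle arrays correlated across genes with r between 0.971 and 0.992, pairs of PA arrays between 0.943 and 0.996 and pairs of combination arrays between 0.963 and 0.995. Genes are not independent replicates, so these values describe the arrays only. After filtering, 19790 items were tested, 11497 of them named genes and 8293 probes without a gene name. Values below are log2 changes ± SE from limma with Benjamini-Hochberg adjusted p-values, and folds are their antilogs. The number of arrays limits the precision.

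The arrays lay 4 to a slide on 12 slides, scanned over 4 days, and the slide set much of the spread. Slide membership accounted for 75.7%, 92.4% and 93.8% of principal components 1, 2 and 3, which held 22.7%, 14.9% and 11.5% of the variance, while the treatment group accounted for at most 0.808% of any of them. The group accounted for 22.3% of component 4. The median residual SD per gene was 0.350 log2 with group means alone and 0.211 with slide as a block, and 0.241 with scan day as a block. Vehicle lay at position 1 on 8 slides, PA at positions 1, 2 and 3 on 4, 12 and 4 arrays, and the combination at positions 3 and 4 on 8 and 12 arrays. Position on the slide thus went with the group. Counts of changed items are therefore given with slide as a block too, as are most list results and the leading genes. Of 181 pairs of gene and comparison named here, 156 had the same call with slide as a block as without it, 25 gained one and 0 lost one. Adding array position to the block left the call of 99 the same, while 1 gained a call, 80 lost theirs and 1 called gene turned direction.

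**Figure D1:**
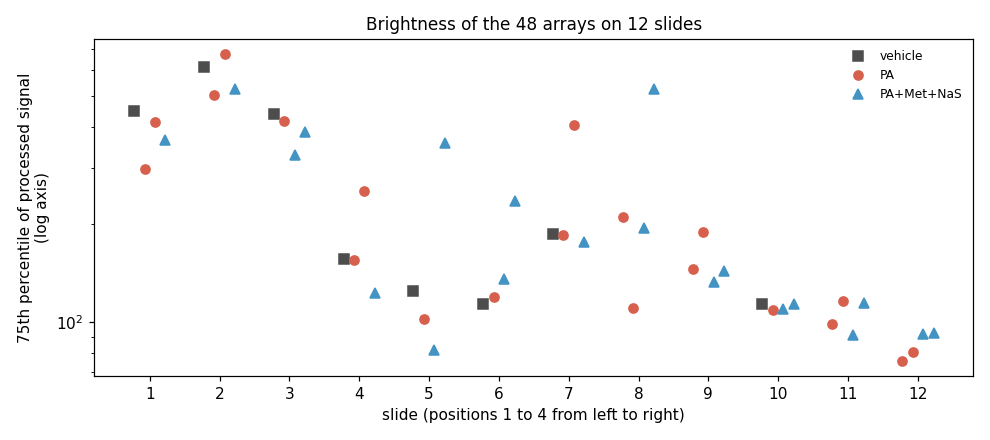
The 75th percentile of processed signal (intensity, log axis) of each of the 48 arrays, by slide, with positions 1 to 4 from left to right and colours for vehicle, PA and PA+Met+NaS. Values range from 75.9 to 672, and PA replicate 11 and combination replicates 7 and 12 lie 2.20, 3.51 and 2.68 times above the median of their slide mates.

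Palmitate alone was compared with vehicle (20 against 8 arrays) to find the transcripts that change with the fatty acid. Angptl4, a secreted inhibitor of lipoprotein lipase and a target of the fatty acid receptor PPAR alpha, rose 1.82-fold (0.86 ± 0.16 log2, adjusted p = 0.00292) and lay above the vehicle mean on 20 of 20 PA arrays. Gucy2c, the guanylate cyclase receptor for guanylin, rose 2.30-fold (1.20 ± 0.19, adjusted p = 0.000394, 20 of 20 arrays). Wnt4, a secreted Wnt ligand, fell by 0.73 ± 0.12 log2 (1.65-fold, adjusted p = 0.000394, 20 of 20 arrays). The slide block gave 0.78 ± 0.08, 1.14 ± 0.14 and -0.65 ± 0.08 for these genes (adjusted p = 1.45e-07, 1.8e-06 and 2.8e-06). As a group, genes of fatty acid oxidation and PPAR alpha targets were higher with a median of 0.20 log2 over 32 measured members (limma's camera, adjusted p = 1.64e-14), 1 of them past limma's threshold alone. Gluconeogenesis had a median of 0.07 over 23 measured members (camera adjusted p = 0.0701), 0 of them past it alone, and the difference between these lists was not tested. In all, 28 of 19790 items changed, 21 higher and 7 lower, with 1518 at an unadjusted p under 0.05.

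Among the other named genes with the largest rises, Gnat2, a transducin subunit best known from cone photoreceptors, rose by 0.87 ± 0.10 log2 (adjusted p = 1.67e-07) and the complement gene C4a by 0.79 ± 0.15 (adjusted p = 0.00347). Myo5b, a myosin of vesicle transport, rose by 0.77 ± 0.13, the carboxylesterase Ces2c by 0.70 ± 0.10 and Afm, which encodes the vitamin E carrier afamin, by 0.70 ± 0.14. Their adjusted p-values were 0.00107, 9.93e-05 and 0.00711. Anxa3, an annexin, rose by 0.67 ± 0.14 (adjusted p = 0.0153), Gde1, a glycerophosphodiester phosphodiesterase, by 0.62 ± 0.09 (adjusted p = 0.000135) and Ech1, a dienoyl-CoA isomerase of fatty acid oxidation, by 0.57 ± 0.12 (adjusted p = 0.0249). Each of these 8 genes lay above the vehicle mean on 20 of 20 PA arrays. Gnat2 stood at 0.93 ± 0.07 and C4a at 0.92 ± 0.10 with slide as a block (adjusted p = 1.72e-10 and 1.35e-07). Only 3 named genes met every condition for the largest falls. Beside Wnt4 these were Unc13c, which primes synaptic vesicles, at -0.93 ± 0.18 (adjusted p = 0.00821, lower on 19 of 20 arrays), and Gas2l3, a linker of actin and microtubules, at -0.45 ± 0.09 (adjusted p = 0.0156). The calls of Anxa3, Ech1 and Gas2l3 were lost without single vehicle arrays. Without vehicle replicate 7 Anxa3 stood at 0.60 (adjusted p = 0.0702), without replicate 4 Ech1 stood at 0.53 (adjusted p = 0.084), and without replicate 8 Gas2l3 stood at -0.41 (adjusted p = 0.0692). In the coordinates of the array files (rn4, 1-based), the probe of Angptl4 lies on chromosome 7 at 16262218 to 16262277, that of Gucy2c on chromosome 4 at 173738809 to 173738868 and that of Wnt4 on chromosome 5 at 156082786 to 156082845.

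In the list of fatty acid oxidation and PPAR alpha targets, 1 of 32 measured genes, Angptl4, passed the threshold over all genes and 7 were higher when adjusted over the list alone. Under the slide block 16 were higher and 0 lower, at a median of 0.22 log2. Acot1, a cytosolic acyl-CoA thioesterase, had 0.48 ± 0.12 (adjusted p = 0.0713) and rose by 0.56 ± 0.07 with slide as a block (adjusted p = 1.8e-06, higher on 8 of 8 slides). Acaa2, a thiolase of mitochondrial beta-oxidation, had 0.42 ± 0.11 (adjusted p = 0.115) and 0.42 ± 0.08 with the block (adjusted p = 0.00103). Etfdh, which passes electrons from beta-oxidation to ubiquinone, had 0.21 ± 0.07 (adjusted p = 0.303) and 0.20 ± 0.06 (adjusted p = 0.0331). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, stood at 0.23 ± 0.08 (adjusted p = 0.373) and at 0.25 ± 0.06 with the block (adjusted p = 0.0109). The call of this list held (adjusted p = 0.000845 with an estimated correlation) and within scan days 1 and 2, where the medians were 0.16 (adjusted p = 0.00104) and 0.31 (adjusted p = 3.06e-13).

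The list of ATF4 targets and the amino acid response, genes induced when translation or amino acid supply is stressed, had a median of 0.20 log2 over 27 members. By limma 0 passed the threshold over all genes and 2 were higher when adjusted over the list alone. The list's camera adjusted p was 5.39e-08, and the call was lost on estimating the correlation (adjusted p = 0.229 with an estimated correlation). Atf3, a stress-induced transcription factor, had 1.36 ± 0.38 (adjusted p = 0.129), with vehicle replicate 6 far below the other vehicle arrays, and 1.37 ± 0.31 with slide as a block (adjusted p = 0.00498). Without that array and without the block Atf3 stood at 0.81 ± 0.30 (adjusted p = 0.427). Asns, asparagine synthetase, had 0.47 ± 0.13 (adjusted p = 0.147) and rose by 0.35 ± 0.08 with the block (adjusted p = 0.00615). Ddit3, the stress factor CHOP, had 0.56 ± 0.22 (adjusted p = 0.448) and 0.51 ± 0.13 (adjusted p = 0.0112). The amino acid transporter chain Slc3a2 had 0.40 ± 0.15 (adjusted p = 0.371) and 0.34 ± 0.08 (adjusted p = 0.00903), and 6 members in all were higher with the block. Within scan days 1 and 2 the medians were 0.27 and 0.08, with adjusted p of 0.00104 and 0.0155. With array position added to the slide block the list did not pass, at a median of 0.14 (adjusted p = 0.235).

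Cell cycle genes had a median of -0.13 log2 over 32 members (camera adjusted p = 1.67e-07, and adjusted p = 0.0527 with an estimated correlation). By limma 0 passed the threshold over all genes and 1 was lower when adjusted over the list alone. The slide block gave a median of -0.11 and 5 lower members. Among these were the mitotic kinesins Kif20a at -0.22 ± 0.05 (adjusted p = 0.00482) and Kif11 at -0.20 ± 0.06 (adjusted p = 0.0405) and the mitotic kinase Plk1 at -0.24 ± 0.06 (adjusted p = 0.0161). Without the block these genes had -0.24 ± 0.07, -0.25 ± 0.09 and -0.32 ± 0.12, with adjusted p of 0.162, 0.355 and 0.373. Within scan days 1 and 2 the list's median was -0.12 (adjusted p = 0.00103) and -0.06 (adjusted p = 0.257). No other list passed the test, and so 3 of 29 lists did, 1 of them with an estimated correlation. By limma's fry, which asks whether the genes of a list move on balance one way, 2 lists passed. Camera with the slide block passed 11 lists, 1 of them with an estimated correlation. The 8 beside those 3 were insulin signalling, oxidative phosphorylation, the tricarboxylic acid cycle, p53 targets, xenobiotic metabolism, urea cycle and amino acid breakdown, proteasome, and autophagy and lysosome. Their medians ran from -0.11 to 0.13, and none kept its call (smallest adjusted p = 0.213 with an estimated correlation). Without vehicle replicates 4, 5, 6 and 8 in turn the number of lists was 5, 11, 8 and 5, and as many as 3 lists passed in 56 of 100 splits of the arrays, the real one included.

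Genes of glucose output and insulin signalling were measured with palmitate as follows. Pck1, the cytosolic enzyme that commits pyruvate and lactate carbon to gluconeogenesis, differed by -0.01 ± 0.29 log2 (adjusted p = 1). A single spot set this value, since the probe used read 2.50 on PA replicate 17 against 6.32 to 7.49 on the other arrays. Without that array Pck1 stood at 0.23 ± 0.11 (adjusted p = 0.604). G6pc1, the catalytic subunit of glucose-6-phosphatase, differed by 0.10 ± 0.07 (adjusted p = 0.855). Over 23 measured members of gluconeogenesis 0 passed by limma over all genes and 0 when adjusted over the list alone, and 3 were higher with slide as a block. The median was 0.07 (camera adjusted p = 0.0701, with slide as a block 0.05 and adjusted p = 0.0827). The glucose transporter Slc2a2 had 0.56 ± 0.22 (adjusted p = 0.447) and rose by 0.54 ± 0.13 with the block (adjusted p = 0.006). The insulin receptor Insr differed by 0.04 ± 0.10 and its substrates Irs1 and Irs2 by -0.19 ± 0.13 and -0.17 ± 0.14, with adjusted p of 1, 0.844 and 0.919. The 22 measured members of insulin signalling had a median of -0.10 (camera adjusted p = 0.164) and, with slide as a block, -0.11 (camera adjusted p = 0.0102, and adjusted p = 0.213 with an estimated correlation). Scd, the stearoyl-CoA desaturase, stood at -0.28 ± 0.09 (adjusted p = 0.201). Pdk4 and Ppargc1a, fixed beforehand, were not among the items tested.

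Among markers of other cell types, 0 of 6 adipocyte markers passed by limma over all genes. Adjusted over the list alone 2 were higher. The list's median was 0.10 log2 (camera adjusted p = 0.0844). Fabp4, the adipocyte fatty acid binding protein, was well above background on 6 PA arrays and 0 vehicle arrays, so no size is given (adjusted p = 0.18, and 9.34e-05 with slide as a block). The macrophage markers had a median of 0.22 over 5 genes (camera adjusted p = 0.529), among them the lysozyme gene Lyz2 at 0.74 ± 0.23 (adjusted p = 0.245, and 0.54 ± 0.14 with adjusted p = 0.0137 with the block). The 5 bile duct cell markers had a median of -0.10 (camera adjusted p = 0.487), with keratin Krt19 at -0.49 ± 0.18 (adjusted p = 0.389, dim on some vehicle arrays, so of uncertain size).

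In the fit with the slide block 1586 items changed, 823 higher and 763 lower, all 28 of the unblocked calls among them with the same sign, and with scan day as a block 813 changed, 326 higher and 487 lower. Within scan days 1 and 2, where 3 vehicle arrays each stood against 5 and 4 PA arrays, limma called 0 and 0 items with 2690 and 1421 at an unadjusted p under 0.05. Scan days 3 and 4 held 1 vehicle array each. With array position added to the slide block 36 items changed, 13 of them among the 28. Other scalings moved the share of higher calls, from 21 higher and 7 lower to 25 and 18 after quantile normalisation, to 21 and 30 after normexp with quantile normalisation and to 20 and 11 with the percentile taken over the spots without an outlier mark.

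**Figure D2:**
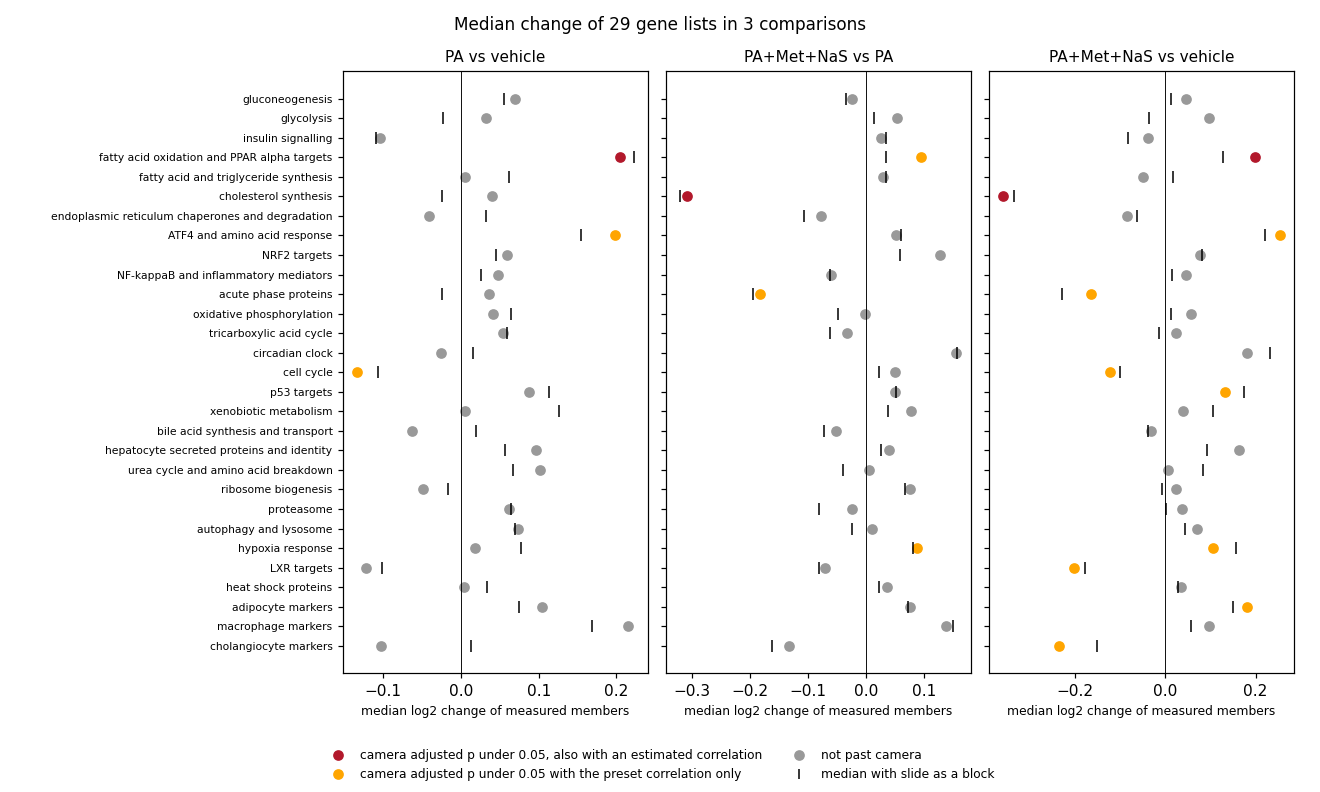
Median log2 change of 29 gene lists in PA against vehicle, PA+Met+NaS against PA and PA+Met+NaS against vehicle (x axis, log2). Dark red points passed camera with a preset and with an estimated correlation, orange points with the preset correlation only, grey points did not pass, and the tick is the median with slide as a block. The median of cholesterol synthesis was -0.31 for PA+Met+NaS against PA, and that of fatty acid oxidation was 0.20 for PA against vehicle.

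PA+Met+NaS was compared with PA (20 against 20 arrays) to find what metformin and salicylate changed in cells that also received palmitate. Genes of cholesterol synthesis fell together, with 12 of 25 measured members lower, 0 higher and a median of -0.31 log2 (camera adjusted p = 1.57e-24). Hp, which encodes the acute phase protein haptoglobin, fell 3.53-fold (-1.82 ± 0.12 log2, adjusted p = 5.65e-16) and was below the PA mean on 20 of 20 combination arrays. Isg15, a ubiquitin-like protein induced by interferon, fell 2.51-fold (-1.33 ± 0.20, adjusted p = 7.12e-06, 19 of 20 arrays). Ehhadh, an enzyme of peroxisomal beta-oxidation, rose 2.19-fold (1.13 ± 0.17, adjusted p = 5.92e-06, 19 of 20 arrays). The slide block gave -1.85 ± 0.09, -1.43 ± 0.16 and 1.15 ± 0.09 for Hp, Isg15 and Ehhadh (adjusted p = 3.2e-17, 1.1e-08 and 2.19e-12). In all, 1028 of 19790 items changed, 574 higher and 454 lower, 230 of them by at least 1.5-fold, with 2907 at an unadjusted p under 0.05.

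The largest rise among named genes was that of Pla2g1b, a secreted phospholipase A2 best known from the pancreas, at 1.31 ± 0.15 log2 (2.48-fold, adjusted p = 1.58e-08, 20 of 20 arrays) and 1.25 ± 0.10 with slide as a block (adjusted p = 1.3e-12). The collagen genes Col16a1 and Col9a2 rose by 1.07 ± 0.18 (adjusted p = 3.57e-05) and 0.98 ± 0.10 (adjusted p = 2.17e-10). The carboxylesterase genes Cesl1 and Ces1e rose by 1.02 ± 0.10 (adjusted p = 2.66e-10) and 0.99 ± 0.11 (adjusted p = 4.09e-09). Ccl9, a chemokine, rose by 0.94 ± 0.16 (adjusted p = 5.05e-05), Cyp26a1, which clears retinoic acid, by 0.89 ± 0.09 (adjusted p = 2.17e-10). Elovl3, a fatty acid elongase, rose by 0.87 ± 0.10 (adjusted p = 3.78e-09) and Sema6b, a semaphorin, by 0.86 ± 0.18 (adjusted p = 0.0016). Col16a1, Ccl9 and Elovl3 were well above background on 18, 18 and 17 of the 20 PA arrays and on all 20 combination arrays.

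Among the largest falls, Lect2, a liver-secreted chemotactic protein, fell 3.09-fold (-1.63 ± 0.16, adjusted p = 2.87e-10) and was well above background on 13 combination arrays and 20 PA arrays. Fabp7, the brain-type fatty acid binding protein, fell by 1.53 ± 0.14 on the log2 scale (adjusted p = 3.75e-11) and Gstm3, a glutathione transferase, by 1.52 ± 0.13 (adjusted p = 7.93e-12). Hsd17b2, which inactivates estradiol and testosterone, fell by 1.30 ± 0.17 (adjusted p = 3.52e-07). Chia, an acidic chitinase, had -1.27 ± 0.27 (adjusted p = 0.00158) and Reg3b, a secreted lectin, -1.24 ± 0.18 (adjusted p = 2.85e-06). The interferon-induced genes Ifit3 and Oasl fell by 1.23 ± 0.25 (adjusted p = 0.000734) and 1.18 ± 0.23 (adjusted p = 0.000417). Each of these 8 genes was below the PA mean on 20 of 20 combination arrays and lower in 12 of 12 slides, and Fabp7 and Ifit3 were well above background on 16 and 18 combination arrays. The probe of Hp lies on chromosome 19 at 39443329 to 39443388 (rn4), that of Isg15 on chromosome 5 at 173034674 to 173034733 and that of Ehhadh on chromosome 11 at 81506762 to 81506821.

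**Figure D3:**
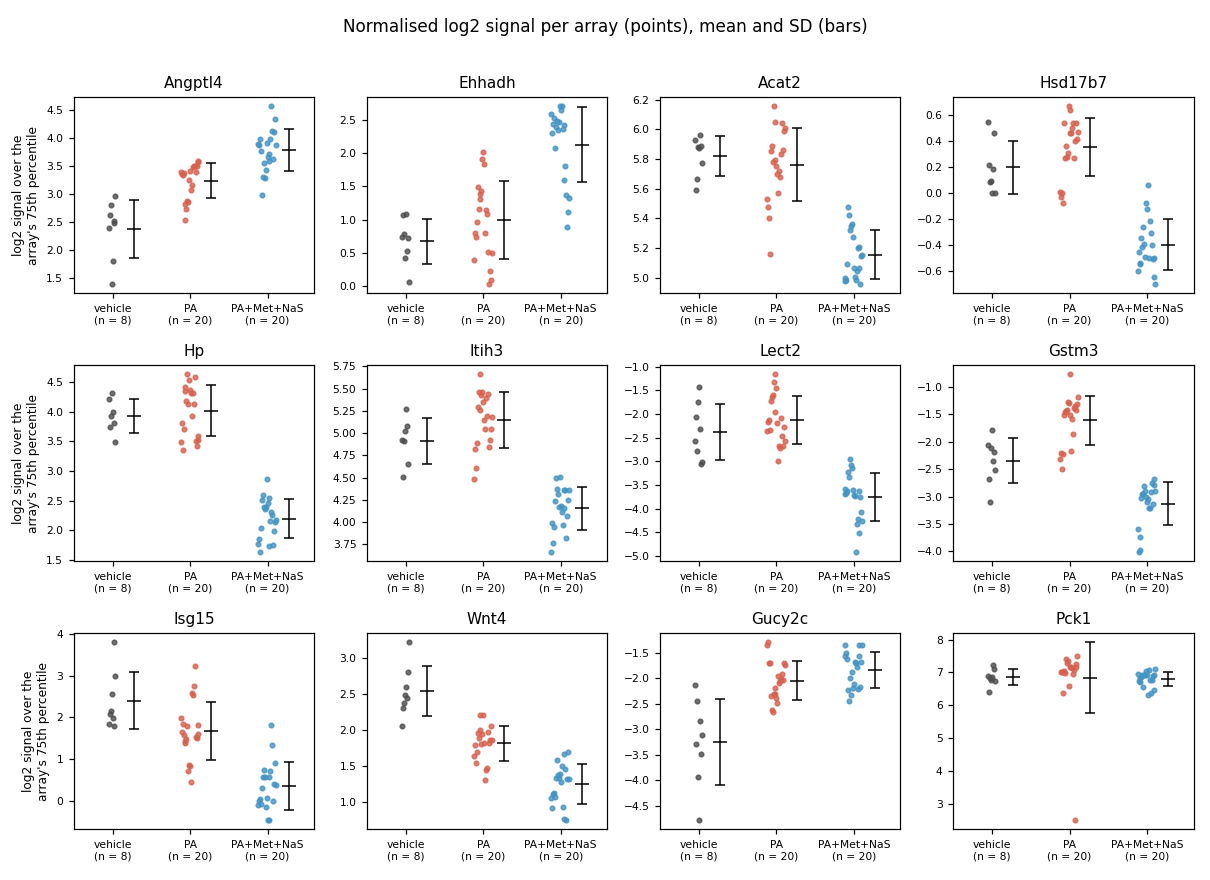
Normalised log2 signal (log2 over the array's 75th percentile) of 12 genes on each array of vehicle (n = 8), PA (n = 20) and PA+Met+NaS (n = 20), with points for arrays and bars for the mean and SD. Hp lay lower on 20 of 20 combination arrays than the PA mean, Angptl4 higher on 20 of 20 PA arrays than the vehicle mean, and 1 PA array read 2.50 for Pck1.

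Adjusted over the list alone, 17 of the 25 cholesterol synthesis genes were lower, and with slide as a block 21 were lower and 0 higher over all genes. Hsd17b7, a sterol reductase of the pathway, fell by 0.75 ± 0.07 log2 (adjusted p = 3.85e-11) and Acat2, the thiolase at its entry, by 0.61 ± 0.07 (adjusted p = 3.78e-09, probe on chromosome 1 at 41939864 to 41939923 in rn4). Fdft1, squalene synthase, fell by 0.48 ± 0.06 (adjusted p = 8.82e-08) and Sqle, squalene epoxidase, by 0.46 ± 0.06 (adjusted p = 1.8e-07), each on 20 of 20 arrays and 12 of 12 slides. Hsd17b7 and Acat2 stood at -0.74 ± 0.06 and -0.64 ± 0.04 with slide as a block (adjusted p = 1.29e-12 and 9.99e-14). The call held (adjusted p = 3.52e-06 with an estimated correlation). It also held within each of the 4 scan days, at medians of -0.23, -0.34, -0.39 and -0.38, and within slides 8, 9, 11 and 12, which held at least 2 arrays of each group, at -0.47, -0.41, -0.37 and -0.49. The largest adjusted p of these 8 was 1.1e-07, and with array position added to the slide block the median was -0.24 (adjusted p = 2.53e-07). Abcg5 and Abcg8, the subunits of the sterol exporter, fell by 0.63 ± 0.11 (adjusted p = 7.44e-05) and 0.52 ± 0.13 (adjusted p = 0.00762), 2 of 8 measured LXR targets, whose list did not pass (camera adjusted p = 0.0991).

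Acute phase proteins are made by the liver in inflammation. Their median was -0.18 log2 over 16 measured members, 4 lower and 1 higher (camera adjusted p = 4.93e-06, and adjusted p = 0.117 with an estimated correlation). The counts were again 4 and 1 when adjusted over the list alone. Beside Hp the lower ones were Itih3 and Itih4, heavy chains of inter-alpha-trypsin inhibitor, at -0.99 ± 0.09 (adjusted p = 1.79e-11) and -0.90 ± 0.13 (adjusted p = 5.64e-06). Cp, the copper carrier ceruloplasmin, stood at -0.90 ± 0.16 (adjusted p = 0.000105). Itih4 also had 1 vehicle array, replicate 8, far below the others, which this comparison does not use. The higher one was Saa4, the constitutively made serum amyloid A, at 0.60 ± 0.11 (adjusted p = 0.000366). Under the slide block 7 members were lower and 1 higher, at a median of -0.20 (adjusted p = 2.98e-05, and adjusted p = 0.172 with an estimated correlation). Within scan days 1 to 4 the medians were -0.08, -0.22, -0.22 and -0.20, and scan day 1 did not pass (adjusted p = 0.0892). With array position added to the slide block the call ended and the median was 0.10 (adjusted p = 0.199). Of 13 measured inflammatory mediators 3 were lower and 0 higher. These were the chemokine Cxcl10 at -0.88 ± 0.20 (adjusted p = 0.00356), the macrophage growth factor Csf1 at -0.35 ± 0.07 (adjusted p = 0.00137) and the apoptosis inhibitor Birc3 at -0.19 ± 0.06 (adjusted p = 0.0388). Adjusted over the list alone 4 were lower, and the list did not pass (camera adjusted p = 0.0991).

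Genes of fatty acid oxidation and PPAR alpha targets went both ways, with 7 higher and 3 lower of 32, and 10 higher and 6 lower when adjusted over the list alone. The median was 0.09 log2 (camera adjusted p = 0.0143, and adjusted p = 0.322 with an estimated correlation). Beside Ehhadh, Acot1 rose by 0.76 ± 0.09 (adjusted p = 1.72e-08) and Pex11a, which acts in peroxisome division, by 0.59 ± 0.08 (adjusted p = 1.15e-06). Angptl4 rose by 0.54 ± 0.12 (adjusted p = 0.00191) and the liver transcription factor Creb3l3 by 0.42 ± 0.09 (adjusted p = 0.00126). Among the lower ones were Cyp4a2, a fatty acid hydroxylase, at -0.45 ± 0.14 (adjusted p = 0.0411) and Acadvl, which starts the mitochondrial oxidation of very long chains, at -0.25 ± 0.07 (adjusted p = 0.0138). Under the slide block 12 were higher and 9 lower, the median was 0.03 and the list did not pass (adjusted p = 0.0993). Within scan days 1 to 4 the medians were 0.20, -0.08, -0.01 and 0.05, and only scan day 1 passed (adjusted p = 0.000252). Quantile normalisation alone (adjusted p = 0.128) and after normexp (adjusted p = 0.1) also ended the call.

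The hypoxia list had a median of 0.09 log2, with 2 of 18 higher over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.00596, and adjusted p = 0.322 with an estimated correlation). The higher ones were Egln1, a prolyl hydroxylase that marks HIF1A for decay, at 0.25 ± 0.06 (adjusted p = 0.00612), and Pdk1, which holds back pyruvate dehydrogenase, at 0.17 ± 0.05 (adjusted p = 0.0158). The slide block gave a median of 0.08 (adjusted p = 0.0196, and adjusted p = 0.503 with an estimated correlation). On scan days 1 to 4 it was 0.17, 0.16, 0.05 and 0.14, the last 2 not past the test (adjusted p = 0.142 and 0.172). Quantile normalisation ended the call (adjusted p = 0.0576). In all 4 of 29 lists passed camera, 1 of them with an estimated correlation, 6 with slide as a block and 1 of those with an estimated correlation, while 9 passed fry. As many as 4 lists passed in 49 of 100 splits of the arrays, the real one included.

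Of 23 measured genes of gluconeogenesis 2 were lower and 0 higher, the same counts when adjusted over the list alone, at a median of -0.03 (camera adjusted p = 0.404, with slide as a block -0.04 and adjusted p = 0.169). These were Slc2a2 at -0.60 ± 0.17 (adjusted p = 0.0189), on 20 of 20 arrays, and Ldhb, a lactate dehydrogenase subunit, at -0.74 ± 0.23 (adjusted p = 0.0496), on 16 of 20. The estimate for Ldhb does not use vehicle arrays, yet its call ended without vehicle replicate 1, 2, 3, 5, 6 or 7 through the shared spread (adjusted p = 0.0502 to 0.0544). Pck1 differed by -0.04 ± 0.22 (adjusted p = 0.981) with all arrays. Without PA replicate 17, whose spot read far below the rest, it fell by 0.28 ± 0.08 on the log2 scale (adjusted p = 0.0294), and its other probe had -0.34 with all arrays. The probe used lies on chromosome 3 at 164017597 to 164017656 (rn4) and was saturated on 6 of the 48 arrays. G6pc1 differed by -0.03 ± 0.06 (adjusted p = 0.936), Insr by -0.08 ± 0.08 (adjusted p = 0.762), Irs1 by -0.14 ± 0.10 (adjusted p = 0.62) and Irs2 by -0.09 ± 0.11 (adjusted p = 0.819). Gys2, the liver glycogen synthase, fell by 0.81 ± 0.21 (adjusted p = 0.011), and Cpt1a and Scd stood at 0.10 ± 0.06 (adjusted p = 0.525) and 0.08 ± 0.06 (adjusted p = 0.712). In the amino acid response list, which did not pass, Asns rose by 0.38 ± 0.10 (adjusted p = 0.013) and Ddit4, an inhibitor of mTOR signalling, fell by 0.63 ± 0.07 (adjusted p = 3.44e-08).

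The circadian clock list had a median of 0.15 log2 over 14 members, 1 higher over all genes and 3 when adjusted over the list alone, and did not pass camera without a block (adjusted p = 0.0504). The 1 was the clock repressor Cry1, which rose by 0.46 ± 0.08 (adjusted p = 4.25e-05). Blocking on slide gave a median of 0.16 with 8 members higher and 2 lower, and the list then passed (adjusted p = 0.0104, and adjusted p = 0.0662 with an estimated correlation), as it did by fry without a block (adjusted p = 0.00877). In scan days 1 to 4 the medians were 0.17, 0.13, 0.11 and 0.14, the last not past the test (adjusted p = 0.172). Within slides 8, 9, 11 and 12 they were 0.19, 0.10, 0.15 and 0.14, and only slide 8 passed (adjusted p = 0.0123). With array position added to the slide block the median was 0.018 (adjusted p = 0.704). Also past camera only with the slide block were ribosome biogenesis and the proteasome at medians of 0.07 and -0.08 (adjusted p = 0.0496 and 0.00189, and adjusted p = 0.172 and 0.503 with an estimated correlation).

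Among markers of other cell types, 2 of 6 adipocyte markers were higher, over all genes and when adjusted over the list alone. Fabp4 rose by 1.21 ± 0.24 log2 (adjusted p = 0.000704, well above background on 15 combination and 6 PA arrays, so of uncertain size) and Cfd, the complement protease adipsin, by 0.88 ± 0.21 (adjusted p = 0.00443). The list's median was 0.08 (camera adjusted p = 0.0808). Of 5 macrophage markers Lyz2 rose by 0.70 ± 0.18 (adjusted p = 0.00916), at a median of 0.14 (camera adjusted p = 0.188). Of 5 bile duct cell markers the transcription factor Sox9 fell by 0.34 ± 0.07 (adjusted p = 0.00166), at a median of -0.13 (camera adjusted p = 0.0568). Adjusted over their lists alone, 2 macrophage markers were higher and 2 bile duct markers lower. The slide block gave medians of 0.07, 0.15 and -0.16 for the 3 lists, none of which passed (camera adjusted p = 0.142, 0.0921 and 0.0989).

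In the fit with the slide block 3733 items changed, 1845 higher and 1888 lower, 1027 of the 1028 unblocked calls among them with the same sign, and with scan day as a block 2940 changed. On scan days 1 to 4 the counts were 672, 145, 161 and 153. Within slides 8, 9, 11 and 12, with 2 arrays of each group, limma called 0 items, with between 898 and 2443 at an unadjusted p under 0.05. The share of higher calls moved with the scaling, from 574 higher and 454 lower to 468 and 589 after quantile normalisation and 457 and 556 after normexp with quantile normalisation. The median of bright probes gave 460 and 576, and 474 and 522 were called with the percentile over the spots without an outlier mark. With array position added to the slide block 449 items changed, 264 of them among the 1028.

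PA+Met+NaS was also compared with vehicle (20 against 8 arrays), which gives the net change with all agents present. Among the largest falls were interferon-induced genes. Isg15 fell by 2.05 ± 0.26 on the log2 scale (4.15-fold, adjusted p = 3.04e-07), Ifit3 by 1.96 ± 0.33 (adjusted p = 5.2e-05) and Oasl by 1.91 ± 0.30 (adjusted p = 1.71e-05), each lower than the vehicle mean on 20 of 20 combination arrays. Genes of fatty acid oxidation and PPAR alpha targets were higher, with 12 of 32 higher and 0 lower at a median of 0.20 log2 (camera adjusted p = 3.1e-12). Genes of cholesterol synthesis were lower, with 12 of 25 lower and 0 higher at a median of -0.36 (camera adjusted p = 1.08e-13). Hp fell 3.32-fold (-1.73 ± 0.16, adjusted p = 1.34e-10). Of 19790 items 1329 changed, 688 higher and 641 lower, 545 of them by at least 1.5-fold, with 3732 at an unadjusted p under 0.05.

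Serpinb6b, an intracellular serine protease inhibitor, rose (adjusted p = 8.83e-10) and was well above background on 20 combination arrays and 2 vehicle arrays. Its fitted change of 1.91 ± 0.19 log2 rests on vehicle values mostly near background, so its size is uncertain. Fgf21, a hormone released by liver under metabolic stress, rose 3.47-fold (1.80 ± 0.45, adjusted p = 0.00894), and the immediate early transcription factor Egr1 rose by 1.49 ± 0.33 (adjusted p = 0.00243). Ehhadh rose by 1.45 ± 0.22 (adjusted p = 1.31e-05) and Lyz2 by 1.44 ± 0.23 (adjusted p = 3.1e-05). Beside the interferon-induced genes, Pbsn, a lipocalin named probasin and known from the prostate, fell (-2.12 ± 0.38, adjusted p = 0.000127, well above background on 8 combination arrays and 8 vehicle arrays). Ubd, a ubiquitin-like protein induced by cytokines, fell by 2.02 ± 0.28 (adjusted p = 1.46e-06, on 6 and 8 arrays). Most combination arrays lay near background for both, so their sizes are uncertain too. With array position added to the slide block Fgf21 stood at -0.36.

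In the fatty acid oxidation list Acot1 rose by 1.24 ± 0.12 log2 (adjusted p = 1.34e-10) and Angptl4 by 1.40 ± 0.16 (adjusted p = 9.84e-09). Pex11a rose by 0.81 ± 0.11 (adjusted p = 4.58e-07), Acaa2 by 0.70 ± 0.11 (adjusted p = 2.28e-05) and Cpt1a by 0.33 ± 0.08 (adjusted p = 0.00966). Adjusted over the list alone 14 were higher, and with slide as a block 15 were higher at a median of 0.13. The call held (adjusted p = 0.00172 with an estimated correlation). In cholesterol synthesis Cyp51, the lanosterol demethylase, fell by 0.79 ± 0.09 (adjusted p = 5.16e-08), Acat2 by 0.66 ± 0.09 (adjusted p = 4.53e-07), Hsd17b7 by 0.59 ± 0.09 (adjusted p = 1.07e-05) and Sqle by 0.54 ± 0.08 (adjusted p = 2.18e-06). Adjusted over the list alone 15 were lower, with slide as a block 16 were lower at a median of -0.33, and the call held (adjusted p = 0.000773 with an estimated correlation). On scan days 1 and 2 the medians of fatty acid oxidation were 0.31 and 0.16 and those of cholesterol synthesis -0.38 and -0.43, with the largest adjusted p at 1.66e-05.

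Of 27 ATF4 and amino acid response genes 4 were higher and 1 lower, and 8 and 1 when adjusted over the list alone, at a median of 0.25 log2 (camera adjusted p = 2.01e-05, and adjusted p = 0.239 with an estimated correlation). Asns rose by 0.85 ± 0.13 (adjusted p = 1.51e-05), Trib3, a pseudokinase that binds AKT, by 0.86 ± 0.22 (adjusted p = 0.0112) and Atf3 by 1.36 ± 0.38 (adjusted p = 0.0184). For Atf3 vehicle replicate 6 lay far below the other vehicle arrays, and the change was 0.81 without it (adjusted p = 0.105). The fourth was Fgf21, which the fatty acid oxidation list holds too, and the lower one was Ddit4 at -0.58 ± 0.10 (adjusted p = 6.05e-05). Acute phase proteins had a median of -0.16, with 3 of 16 lower and 1 higher over all genes and 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00333, and adjusted p = 0.239 with an estimated correlation). Beside Hp the lower ones were Itih3 at -0.76 ± 0.12 (adjusted p = 2.66e-05) and Cp at -0.93 ± 0.21 (adjusted p = 0.00282), and Saa4 rose by 0.64 ± 0.16 (adjusted p = 0.00778). In the blocked fit the medians of both lists were 0.22 and -0.23 (adjusted p = 5.27e-05 and 0.000546, and adjusted p = 0.214 and 0.234 with an estimated correlation). On scan days 1 and 2 they were 0.21 and 0.22 for the amino acid response (adjusted p = 0.0176 and 1.22e-06). For acute phase proteins scan day 1 did not pass (adjusted p = 0.0635) while scan day 2 had a median of -0.42 (adjusted p = 0.000147). Cxcl10 fell 3.26-fold (-1.71 ± 0.27, adjusted p = 1.55e-05).

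A further 6 lists passed camera without a block, all of them lost with an estimated correlation. Cell cycle genes had a median of -0.12 log2, 2 of 32 lower in each adjustment (camera adjusted p = 0.017, and adjusted p = 0.374 with an estimated correlation). These were Kif11 at -0.34 ± 0.09 (adjusted p = 0.0118) and Kif20a at -0.26 ± 0.07 (adjusted p = 0.0125). Targets of p53 had a median of 0.13, 2 of 15 higher (camera adjusted p = 0.0202, and adjusted p = 0.239 with an estimated correlation). The higher ones were Ccng1, cyclin G1, at 0.39 ± 0.10 (adjusted p = 0.0104) and the antiproliferative gene Btg2 at 0.58 ± 0.17 (adjusted p = 0.0262). The hypoxia list had a median of 0.11, 2 of 18 higher (camera adjusted p = 0.0171, and adjusted p = 0.374 with an estimated correlation). The higher ones were Pdk1 at 0.20 ± 0.06 (adjusted p = 0.0304) and Ndrg1, a stress-response gene, at 0.51 ± 0.16 (adjusted p = 0.0393). Both calls were lost without single vehicle arrays, Pdk1 standing at 0.19 without replicate 2 (adjusted p = 0.0788) and Ndrg1 at 0.42 without replicate 5 (adjusted p = 0.132). LXR targets had a median of -0.20 over 8 genes (camera adjusted p = 0.019, and adjusted p = 0.161 with an estimated correlation). Abcg5 fell by 0.81 ± 0.14 on the log2 scale (adjusted p = 0.000137) and Abcg8 by 0.62 ± 0.17 (adjusted p = 0.02). Adjusted over each list alone the counts of these 3 were again 2. In the blocked fit the p53 and hypoxia lists passed at medians of 0.17 and 0.16 (adjusted p = 0.0099 and 0.00931, and adjusted p = 0.159 and 0.393 with an estimated correlation), and the cell cycle and LXR lists did not (adjusted p = 0.0537 and 0.0537). On scan days 1 and 2 the cell cycle medians were -0.07 and -0.01, those of p53 targets 0.24 and 0.04, those of hypoxia 0.38 and 0.10 and those of LXR targets -0.09 and -0.19. Only p53 targets and hypoxia on scan day 1 passed there (adjusted p = 0.0264 and 0.00617). Quantile normalisation alone and after normexp ended the calls of p53 targets (adjusted p = 0.093 and 0.065) and of hypoxia (adjusted p = 0.127 and 0.168).

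The other 2 of the 6 were markers of other cell types. Adipocyte markers had a median of 0.18 log2 with 2 of 6 higher in each adjustment (camera adjusted p = 0.0122, and adjusted p = 0.135 with an estimated correlation). Fabp4 was not well above background on any vehicle array and was so on 15 combination arrays, so its change is at least 0.99 log2 (adjusted p = 1.85e-06), and Cfd rose by 0.84 ± 0.27 (adjusted p = 0.0498). Bile duct cell markers had a median of -0.24, with 2 of 5 lower (camera adjusted p = 0.0485, and adjusted p = 0.135 with an estimated correlation). Sox9 stood at -0.49 ± 0.10 (adjusted p = 0.000844) and Krt19 at -0.87 ± 0.18 (adjusted p = 0.00126, well above background on 3 combination and 5 vehicle arrays). Adjusted over the list alone 3 bile duct markers were lower and 1 higher. Neither list passed with slide as a block (adjusted p = 0.0817 and 0.193) or within scan days 1 and 2. Quantile normalisation alone (adjusted p = 0.0806) and after normexp (adjusted p = 0.113) ended the call of the bile duct markers. The macrophage markers had a median of 0.10 over 5 genes and did not pass (camera adjusted p = 0.16).

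Pck1 differed from vehicle by -0.05 ± 0.29 log2 (adjusted p = 0.963), G6pc1 by 0.08 ± 0.07 (adjusted p = 0.651) and Insr by -0.04 ± 0.10 (adjusted p = 0.894). Irs1 and Irs2 had -0.32 ± 0.13 (adjusted p = 0.136) and -0.26 ± 0.14 (adjusted p = 0.314). In the blocked fit both fell, by 0.34 ± 0.11 (adjusted p = 0.0259) and 0.29 ± 0.09 (adjusted p = 0.0209). Scd stood at -0.21 ± 0.09 (adjusted p = 0.158). In xenobiotic metabolism, a list that passed with slide as a block (median 0.11, adjusted p = 0.0348, and adjusted p = 0.393 with an estimated correlation) and not without it (camera adjusted p = 0.0638), 4 of 16 genes were higher and 5 when adjusted over the list alone. Among them were Ces2c at 0.90 ± 0.10 (adjusted p = 2.14e-08) and the cytochrome Cyp3a9 at 0.66 ± 0.15 (adjusted p = 0.0039).

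In the fit with the slide block 4442 items changed, 2228 higher and 2214 lower, 1326 of the 1329 among them with the same sign, with scan day as a block 3535, and within scan days 1 and 2 2139 and 66. Camera passed 10 of 29 lists, 8 with slide as a block, 2 with an estimated correlation in either fit and 9 by fry. Leaving out single vehicle arrays ended the calls of Cfd (0.75 without vehicle replicate 7, adjusted p = 0.124), Btg2 (0.50 without replicate 7, adjusted p = 0.086) and Abcg8 (-0.51 without replicate 1, adjusted p = 0.0742). The scaling moved the share of higher calls, from 688 higher and 641 lower to 646 and 919 after quantile normalisation and 561 and 969 with normexp before it. The median of bright probes gave 582 and 877, and the percentile over spots without an outlier mark 556 and 813. Position cannot be separated well from this comparison, since vehicle lay at 1 and the combination at 3 and 4. With position added to the slide block 106 items changed, 92 of them among the 1329, and 5 of 10 lists no longer passed. These were the amino acid response at a median of -0.01 (adjusted p = 0.853), acute phase proteins at 0.04 (adjusted p = 0.228), p53 targets at 0.11 (adjusted p = 0.731), LXR targets at 0.08 (adjusted p = 0.354) and adipocyte markers at 0.05 (adjusted p = 0.738).

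The last question was whether genes changed by palmitate moved back when metformin and salicylate were added. Cdhr5, a protocadherin of the brush border, was the only gene of the naming rule that did so without a block. It rose by 0.44 ± 0.10 log2 with palmitate (adjusted p = 0.0355) and was lower by -0.24 ± 0.07 with the combination against PA (adjusted p = 0.0435). The calls were lost without single arrays, the first at 0.36 without vehicle replicate 4 (adjusted p = 0.148) and the other at -0.23 without PA replicate 17 (adjusted p = 0.0588). Of 28 items changed by palmitate, 13 changed again in the combination against PA, 2 in the opposite direction and 11 in the same. The other opposite one was RGD1564165, chosen after its values were seen, at -0.29 and then 0.17 log2. Without vehicle replicates 1, 3, 4, 6, 7 and 8 in turn the number of opposite ones was 1. Independent lists of these sizes would share 0.482 genes up then down, 0.203 down then up, 0.609 up then up and 0.161 down then down, against 1, 1, 9 and 2 found.

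Genes that moved further in the same direction included Angptl4 (0.86, then 0.54), Gnat2 (0.87, then 0.48 ± 0.07 with adjusted p = 8.09e-06), Myo5b (0.77, then 0.35 ± 0.10 with adjusted p = 0.0216) and Gde1 (0.62, then 0.23 ± 0.07 with adjusted p = 0.0471). Wnt4 fell further (-0.73, then -0.57 ± 0.09 with adjusted p = 1.13e-05). Gde1 was no longer called without PA replicate 17 (0.21, adjusted p = 0.0683). A further 4 rose in both comparisons and were chosen after their values were seen. Serpinb6b rose by 1.30 ± 0.19 with palmitate (adjusted p = 9.93e-05, well above background on 14 PA and 2 vehicle arrays, so of uncertain size) and by a further 0.61 ± 0.15 (adjusted p = 0.00526). The peroxisomal thioesterase Acot5 rose by 0.37 ± 0.08 and 0.57 ± 0.06 (adjusted p = 0.0206 and 1.18e-09). Adtrp, a hydrolase of lipid esters, rose by 0.56 ± 0.12 and 0.29 ± 0.09 (adjusted p = 0.0196 and 0.0439). Sema3b, a secreted semaphorin with vehicle replicate 6 far below the other vehicle arrays, rose by 0.56 ± 0.10 and 0.32 ± 0.08 (adjusted p = 0.00365 and 0.00711). Without single vehicle arrays the palmitate calls of Acot5 (0.30 without replicate 5, adjusted p = 0.111) and Adtrp (0.50 without replicate 2, adjusted p = 0.0753) were lost.

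In the fit with the slide block 502 items changed in both comparisons, 226 in opposite directions and 276 in the same. These became 2 and 3 with array position added to the block, so position cannot be set aside for the genes below. Genes named from this fit are an extension of the naming rule made after the data were seen. Gstm3 rose by 0.69 ± 0.12 log2 with palmitate (adjusted p = 0.000238) and then fell by 1.56 ± 0.09 (adjusted p = 6.76e-16). Sds, the serine dehydratase of amino acid breakdown, had 0.62 ± 0.10 (adjusted p = 0.000263) and -0.73 ± 0.08 (adjusted p = 5.06e-09). Lect2 had 0.55 ± 0.13 (adjusted p = 0.00826) and -1.66 ± 0.10 (adjusted p = 2.9e-15). Chia had 1.02 ± 0.32 (adjusted p = 0.0442) and -1.40 ± 0.24 (adjusted p = 3e-05), with vehicle replicate 1 far below the other vehicle arrays. Without that array and without the block the palmitate change of Chia was 0.33 ± 0.19 (adjusted p = 0.686), against 1.02 ± 0.36 with it, so most of that size came from 1 array, and the block was not tried without it. In the other order, Masp1, a protease of the lectin complement pathway, had -0.44 ± 0.11 (adjusted p = 0.00956) and 0.64 ± 0.08 (adjusted p = 1.46e-07), and Pla2g1b had -0.41 ± 0.13 (adjusted p = 0.0417) and 1.25 ± 0.10 (adjusted p = 1.3e-12). Among the genes that passed with palmitate in this fit and not without the block were chemokines. Ccl5 stood at -0.98 ± 0.21 (adjusted p = 0.00358, well above background on 13 PA arrays) and without the block at -0.89 ± 0.25 (adjusted p = 0.139). Cxcl10 stood at -0.85 ± 0.22 (adjusted p = 0.014) and without the block at -0.83 ± 0.27 (adjusted p = 0.263), and it fell again in the combination. Without the block the palmitate changes of Gstm3, Sds, Lect2, Chia, Masp1 and Pla2g1b had adjusted p of 0.0577, 0.115, 0.927, 0.347, 0.159 and 0.701.

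**Figure D4:**
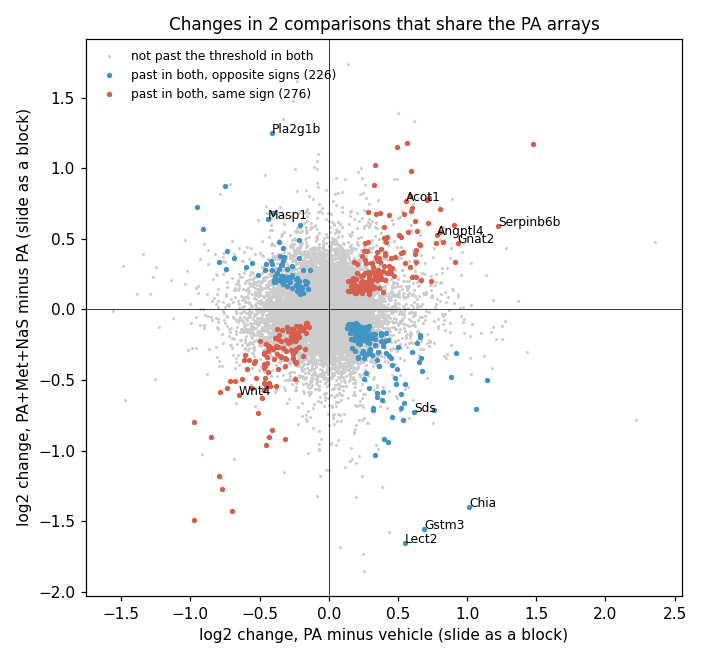
Log2 change of each of 19790 items with slide as a block, PA minus vehicle on the x axis and PA+Met+NaS minus PA on the y axis. Blue points (226) passed both tests with opposite signs, red points (276) passed both with the same sign, and grey points are the rest.

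Both comparisons use the same 20 PA arrays, which pulls their changes apart by chance alone. In 50 simulated draws without any effect the correlation across genes averaged -0.326 (range -0.667 to 0.235) and the covariance -0.00821, against an observed 0.059 and 0.00229. Under the slide block the simulated values averaged -0.33 and -0.00482 and the observed ones were -0.00102 and -4.05e-05. Independent lists would share 78.5, 71.1, 76.7 and 72.8 items up then down, down then up, up then up and down then down with slide as a block, against 152, 74, 160 and 116 found. When odd-numbered PA arrays were set against vehicle and even-numbered ones against the combination, and the other way round, limma gave 0 and 0 opposite calls and 4 and 5 calls in the same direction. With the slide block these were 90 and 72, and 212 and 135. Scan days 1 and 2 had 0 palmitate calls each, so no gene could move back there.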

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

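The tests of array position and of bright arrays, and the splits made within slides, were chosen only after the results they bear on had been seen.

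In the vehicle group, the only one with 10 arrays or fewer, 6 of 118 measures had 1 array far from the other 7, where chance alone gives about 1 in 20. The value is the gap to the nearest array as a share of the group's range (n = 8). For the chitinase gene Chia it was 0.822, with replicate 1 at -5.87 log2 against -0.87 for the nearest array. Sema3b had 0.758, with replicate 6 at 1.09 against 2.05. For Atf3 it was 0.661, again with replicate 6, at -3.16 against 0.18. Itih4 had 0.581, with replicate 8 at 3.40 against 3.97, and the complement protease gene C1s had 0.567, with replicate 8 at 5.43 against 5.74. The slope of the spike-in fit gave 0.616, with replicate 4 at 0.904 against 0.981.

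With slide as a block, 1586 items differed between PA and vehicle, among them 16 higher genes of fatty acid oxidation. Vehicle lay at position 1 on each of its slides, so position could imitate the change. On the 4 slides with PA at positions 1 and 2, PA at position 2 differed from PA at position 1, in the direction of the called changes, by -0.0630 of their mean size of 0.38 log2 (standard error 0.0892, range -0.266 to 0.158). This argues against a step from position 1 to 2 as the source of most of the change. With position added to the slide block 36 items were called, and a position effect on part of the genes, the day of culture and the treatment itself stay open.

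With slide as a block, 3733 items differed between PA+Met+NaS and PA, among them 21 lower genes of cholesterol synthesis. The combination lay on average 1.6 positions later on the slide. Within a group and slide, the step to the next position, carried over that distance, came to 0.0411 of the mean called change of 0.29 log2 (standard error 0.0397, 12 slides, range -0.213 to 0.291), which argues against position as the source of most of it. PA replicate 11 and combination replicates 7 and 12 were 2.20, 3.51 and 2.68 times as bright as the median of their slide mates, and without these 3 arrays 89.4% of the items (3338) stayed called with the same sign, so brightness may account for few of them. With position added 449 items were called, and position effects on part of the genes, culture day and the drugs themselves stay open.

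Other splits of the arrays were drawn 100 times for each result, the real one included. For PA against vehicle 2 of 100 splits called as many genes as the real one. There were 30 real calls and 363 in the highest other split. That split held 1 of the 8 vehicle arrays in its vehicle group and took 4 of its 8 arrays from 1 scan day. It called several times the real number, which points to a structure of the samples, so chance stays open. Within slides 1 of 100 did, with 1647 real calls against 927 in a split that moved the label of 1 vehicle array, and chance can be excluded. For PA+Met+NaS against PA 1 of 100 did, with 1042 against 0, and within slides 1 of 100, with 3749 against 1, so chance can be excluded in both. For PA+Met+NaS against vehicle 1 of 100 did, with 1352 against 1307, too close to exclude chance. The split with 1307 calls kept 2 vehicle labels and took 5 of its 8 arrays from 1 scan day. Within slides 1 of 100 did, with 4507 against 2462 in a split that kept 7 of 8 vehicle labels, so chance can be excluded. For genes that moved back 1 of 100 splits gave as many, with 3 against 0. Splits of all arrays remove both treatment effects, so hardly any gene can be called in both comparisons and the count decides nothing about moving back. Odd-numbered and even-numbered PA arrays used apart gave 0 and 0 opposite calls.

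For the number of gene lists past camera, chance cannot be excluded in PA against vehicle (56 of 100 splits gave as many, 3 real against 10 in the highest other) or within slides (11 of 100, 11 against 16). The same holds for PA+Met+NaS against PA (49 of 100, 4 against 13), within slides (21 of 100, 5 against 10), and for PA+Met+NaS against vehicle within slides (16 of 100, 8 against 11). Without a block, PA+Met+NaS against vehicle had 10 lists against 9 in the highest other split (1 of 100), too close to exclude chance.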

How the results depend on the processing

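The fits with array position, with slide and another choice together, without the 3 brightest arrays, without PA replicate 17 and with the percentile over spots without an outlier mark were chosen only after the data had been seen. Where a count moved or a direction turned, the cause was not tested, except that smaller samples enter the fits within slides and days and that the 1.5-fold minimum removes small changes. For PA against vehicle the 28 calls became 25 to 35 under 7 alternatives and 34 without PA replicate 17. With slide and position there were 36, 13 of them among the 28. Normexp was always followed by quantile normalisation, so its own part is not known. The calls became 16 at 1.5-fold or more, 51 with normexp and quantile, 43 with quantile normalisation, 17 with no filter on dim probes, 13 with only the 2 groups in the fit and 83 with array weights. With slide as a block there were 1586, with scan date 813, and slide gave 1605 without the 3 brightest arrays, 1524 with quantile normalisation and 1597 with normexp and quantile. On scan days 1 and 2 taken alone limma called 0 and 0, with 2690 and 1421 at an unadjusted p under 0.05. For PA+Met+NaS against PA the 1028 calls became 753 to 1057 under 11 alternatives and 1054 without PA replicate 17. They became 230 at 1.5-fold, 1616 with array weights, 3733 with slide, 2940 with scan date, and with slide 3600 without the brightest arrays, 3833 with quantile normalisation, 3717 with normexp and quantile and 449 with position. Scan days 1 to 4 taken alone gave 672, 145, 161 and 153, and within slides 8, 9, 11 and 12 limma called 0, 0, 0 and 0, with 898 to 2443 at an unadjusted p under 0.05. For PA+Met+NaS against vehicle the 1329 calls became 1068 to 1565 under 12 alternatives, 545 at 1.5-fold, 842 with no filter, 4442 with slide, 3535 with scan date, and with slide 4643 without the brightest arrays, 4552 with quantile normalisation, 4522 with normexp and quantile and 106 with position. Scan days 1 and 2 taken alone gave 2139 and 66.

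The number of lists past camera for PA against vehicle (3) was 2 to 4 under 15 alternatives, 5 with no filter, 11 with slide, 6 with scan date, 8 within scan day 1, 13 with slide without the brightest arrays, 5 with slide and position, 5 without PA replicate 17 and 1 with an estimated correlation. For PA+Met+NaS against PA (4) it was 3 to 6 under 17, 5 without PA replicate 17, 10 with normexp and quantile, 8 with no filter, 8 with the mean of a gene's probes, 7 with the deposited value table, 7 and 12 within scan days 1 and 2, 7 and 2 within slides 8 and 12, 8 with slide without the brightest arrays, 8 with slide, normexp and quantile, 9 by fry and 1 with an estimated correlation. For PA+Met+NaS against vehicle (10) it was 8 to 12 under 20, 6 within scan day 2 and 2 with an estimated correlation. Over 5 scalings the medians of lists past the test kept their sign in 15 of 15, 20 of 20 and 50 of 50 cases and passed in 15, 17 and 44. The number that moved back (2) was 3 and 3 with the mean of a gene's probes and the deposited value table, 2 with slide and position, 0 at 1.5-fold, 7 with normexp and quantile, 5 with quantile normalisation, 5 with the median of bright probes, 0 with no filter, 5 with probes above background on all arrays, 0 with only 2 groups, 10 with array weights, 1 with trend and robust eBayes, 226 with slide, 88 with scan date, 0 and 0 within scan days 1 and 2, 4 with the percentile over unmarked spots, 1 without the brightest arrays, 202 with slide without them, 225 with slide and quantile normalisation, 217 with slide, normexp and quantile, 4 without PA replicate 17, and 0 and 0 when odd or even PA arrays met vehicle.

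Leaving out each vehicle array gave 20 to 30, 993 to 1049 and 950 to 1271 calls, 3 to 11, 4 to 5 and 9 to 11 lists in the same order, and 1 to 2 genes that moved back. The lists of PA against vehicle were 5, 11, 8 and 5 without vehicle replicates 4, 5, 6 and 8, and the genes that moved back numbered 1 without vehicle replicates 1, 3, 4, 6, 7 and 8. Whether equal replicate numbers pair the arrays stays open. Of pairs with equal numbers, 5 of 8 of vehicle and PA, 19 of 20 of PA and combination and 5 of 8 of vehicle and combination correlated above 0.1, and 2, 9 and 3 arrays correlated best with their own number. Of these pairs 1, 10 and 3 shared a slide, and arrays of PA and combination had a median r of 0.520 on the same slide and -0.0724 on others. With the replicate block the counts were 4, 2855 and 1117 genes, 5, 6 and 6 lists and 0 moved back. Of 181 pairs of a named gene and a comparison, 4896 values kept direction and side of the threshold over all alternatives, 799 were no longer past it, 126 newly passed it, 7 moved and 5 turned. These were Fabp4 at -0.28 within slide 12 (adjusted p = 0.917), Cdhr5 at 0.057 within slide 11 (adjusted p = 0.996) and Egr2 at -0.019 within scan day 1 (adjusted p = 0.974), in PA+Met+NaS against PA, and against vehicle Fgf21 at -0.36 with slide and position (adjusted p = 0.858) and Cyp3a9 at -0.048 within scan day 2 (adjusted p = 0.918). Signal over background limits dim probes, for which the number of arrays well above it is given, though not at every mention.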

Other observations

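The 3 classes of genes below were chosen only after the leading genes had been seen, and were tested on the members that the naming rule had not taken. Single members are named after their values were seen.

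Complement and coagulation factors, plasma proteins secreted by the liver, were lower with the combination than with PA. Of 35 tested members (38 measured of 44) 8 were lower and 0 higher, and with slide as a block 19 were lower and 0 higher at a median of -0.22 log2. Vtn, which encodes vitronectin, fell by 1.08 ± 0.10 on the log2 scale (adjusted p = 1.31e-10), coagulation factor F10 by 0.97 ± 0.11 (adjusted p = 1.72e-08), complement factor Cfb by 0.79 ± 0.12 (adjusted p = 1.57e-05) and F7 by 0.78 ± 0.13 (adjusted p = 2.37e-05). Vtn and F10 lay below the PA mean on 20 of 20 combination arrays. C1s fell by 0.42 ± 0.07 (adjusted p = 9.15e-05), and 1 vehicle array that this comparison does not use lay far below the others for it. Masp1, a member outside the tested 35, rose by 0.66 ± 0.09 (adjusted p = 2.01e-06). A lower class as a whole was the hypothesis, and limma's camera with an estimated correlation gave p = 3.57e-05 with slide as a block and 9.23e-05 without it. Against vehicle the class had a median of -0.10 without the block (p = 0.0455), and with it 11 members were lower and 4 higher at a median of -0.18 (p = 0.0418). With palmitate alone the class had a median of 0.11 against vehicle with the block, 7 members higher and 1 lower (p = 0.0254), and 0.12 with 0 called without it (p = 0.102). A2m, C3, Fga, Fgb and Fgg stand in the acute phase list too. The class was not tested with array position in the fit.

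Genes induced by interferon had a median of -0.09 log2 with slide as a block in the same comparison, 13 of 35 tested members lower and 2 higher (40 measured of 52). Camera with an estimated correlation gave p = 0.0514, so a lower class as a whole stays undecided, and without the block p = 0.0307. Rsad2, the antiviral enzyme viperin, fell by 1.01 ± 0.28 (adjusted p = 0.0174) and Irf7, a regulator of interferon genes, by 0.31 ± 0.06 (adjusted p = 0.000128), while Ifi44 and Lgals3bp rose by 0.28 ± 0.08 (adjusted p = 0.0137) and 0.29 ± 0.08 (adjusted p = 0.0138). Against vehicle the median was -0.11 and 7 members were lower without the block (p = 0.0135), and 14 lower and 5 higher with it (p = 0.0467). Immediate early genes, which respond to growth factors and stress within minutes, had 4 of 21 tested members higher and 1 lower with slide as a block (26 measured of 30), at a median of 0.16. Camera with an estimated correlation gave p = 0.229, so a higher class as a whole stays undecided. Egr2 rose by 0.85 ± 0.24 (adjusted p = 0.0214) and stood at -0.019 within scan day 1.

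Against vehicle the immediate early class had a median of 0.33 with 4 members higher without the block (p = 0.0216) and 0.26 with 9 higher with it (p = 0.0428). Dusp1, a phosphatase of MAP kinases, rose by 0.96 ± 0.20 (adjusted p = 0.00143), Egr2 by 1.03 ± 0.32 (adjusted p = 0.0363), Ccn2 by 0.91 ± 0.29 (adjusted p = 0.0429) and Ccn1 by 0.84 ± 0.23 (adjusted p = 0.0181). Without vehicle replicate 7 the calls of Egr2 (0.84, adjusted p = 0.124), Ccn2 (0.74, adjusted p = 0.14) and Ccn1 (0.68, adjusted p = 0.0753) were lost. The same happened to Egr2 without replicates 2, 5 and 8 (adjusted p = 0.0667, 0.0693 and 0.0664), to Ccn2 without replicates 1, 2, 3 and 8 (adjusted p = 0.118, 0.0957, 0.0806 and 0.0907) and to Ccn1 without replicate 1 (adjusted p = 0.0563).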
